A study of Oryza sativa Japonica Group and Oryza sativa Indica Group with 33 samples.

How the data were processed

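Leaf RNA of 6 rice cultivars was measured on 33 single-colour (Cy3) Agilent arrays of design 015241, which carry 60-base oligonucleotide probes. Each sample was a pool of 5 plants of 1 cultivar from 1 independent growth experiment, per the labels. Of the samples given here, 33 were analysed, in 12 groups of a cultivar and a treatment, with 3 arrays per group except IR62266 control (1 array) and Nipponbare control (2 arrays). The labels give replicate numbers, and arrays of different cultivars with the same treatment and the same number were taken as 1 growth experiment, which makes 6 experiments. The labels do not say which cultivar belongs to which tolerance class, so no classes were compared. The hour of harvest is not given in the sources used here.

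The scanner files hold, per the file headers, the output of Agilent Feature Extraction: the processed signal intensity of each spot, which the software had background-subtracted and detrended within the array, with the mean signal, the local background and flags for spots well above background, saturated or outlying. These intensity values were not normalized between arrays, per the file headers. The arrays were read with 2 protocol versions of that software, here called series GE1_105 (16 arrays on 4 slides) and series GE1_107 (17 arrays on 5 slides), and scan day coincided with the series. The authors' value table holds log2 values, which the submitters' labels do not describe. Set against the scanner files, its entries equalled log2 of the mean signal minus the local background median (within 0.001) for about 63.9% of probes in the columns that matched, with no scaling between arrays (column medians ran from 5.27 to 8.57). How the remaining entries were made is not given in the sources used here. Of its 33 columns, 25 matched their own array, 7 matched another array and 1 matched none, so 8 columns were used in no comparison. These were all columns of IR57311 and those of IR72 at high night temperature, replicates 2 and 3. Some matches crossed treatment or cultivar, as the last of these columns held the values of the array of IR57311 control 1. The labels of the scanner files were taken as right. The table served only as an alternative.

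The main value was log2 of the processed signal minus the array's own 75th percentile. Control spots (1417 per array), 510 further spots with control names and outlier spots (7 to 194 per array) were left out, saturated spots were kept (there were none), and spots of 1 probe were averaged. Of 42426 distinct probes, 1 probe per locus was kept, the one with the highest mean over all arrays, and probes without a locus stayed separate. Where the number of arrays well above background is given for a gene, any of its probes counted. A probe was tested when it was well above background on every array of at least 1 group of 2 or more arrays, which left 20577 probes for 20508 loci, called genes below. Of the 559 loci called in the averaged effect, 196 had another measured probe, and 2 of those 302 other probes had the opposite sign. The 75th percentile of the signal ran from 214 to 2288 units, the local background from 15.8 to 32.9 units, and the share of spots well above background from 57.1% to 74.7%. For arrays, precision is limited by their number. Locus names and products are those of the array files, on build IRGSP5, and gene symbols come from lists fixed beforehand. The reference gene table of assembly ASM3414082v1 matched 0 of the loci, so old names were kept. Principal components were taken over the 20341 genes without a missing value. Because cultivars differ in sequence, a low signal can also come from differences under a probe.

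Tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and all p-values are two-sided unless an F-test is named. A linear model held the 12 groups and the array series. The effect averaged over cultivars and the interaction of cultivar and treatment had the experiment as a random block (duplicateCorrelation, estimated correlation 0.421). The effect in each cultivar and the moderated F-test over the 6 control groups used the same fit without the block. Lone arrays were assumed to vary like the other groups. For the 2 comparisons of subspecies, limma was run on 1 value per cultivar, 3 against 3. Where a probe was not well above background on any array of a group, the difference is given as a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

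Altogether 35 gene lists, fixed before the data were examined, were tested with cameraPR (preset correlation 0.01), camera with an estimated correlation, and fry. They include seed storage, floral organ and cell division lists as markers of other tissue. Genes named in the text were chosen by a rule fixed at the same time. For the averaged effect these are the 12 largest rises and 12 largest falls past the threshold with the same sign in at least 5 cultivars. For a cultivar they are the 4 largest rises and 4 largest falls, for the interaction the 10 lowest p-values, for subspecies the 6 highest and 6 lowest differences, for the control groups the 6 lowest p-values, and for a list up to 4 members past the threshold. All clock, flowering and CBF members may be named. The result of 1 flowering list member is not reported here. Loci without a named product were passed over.

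The procedure was tested on simulated data made from 20341 genes, with 100 genes changed 2-fold and 100 changed 4-fold and an experiment correlation of 0.4. For the averaged effect 53% of the 2-fold and 86% of the 4-fold changes were recovered, with 14 other genes called. Without the experiment block 1413 other genes were called, and with 1 value per experiment 2% and 58% were recovered with 0 others. For single cultivars the recovered share of 2-fold changes ran from 11% (IR62266) to 30% (M202) and that of 4-fold changes from 45% to 66%, with 3 to 14 other genes called. For a change in 1 cultivar the interaction test recovered 5% and 46%, with 3 others. The test of the subspecies difference in the temperature effect recovered 0% and 45%, that of the subspecies difference in level 60% and 94%, each with 2 others, and the F-test over control groups 18% and 60% with 0 others. A simulated list of 40 raised genes was called, and a list of 40 unchanged genes was not. The simulated genes varied independently of each other, with the same spread between experiments under both treatments. In the real data 11795 genes differed among the high night temperature experiments and 2329 among the control experiments. The numbers of other genes called and the check of lists therefore do not measure the error rate in the real data.

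Alternatives were quantile normalization, normexp background correction (offset 50), the authors' value table, other filters on dim probes, the series, slide, experiment and replicate number as other terms, each series alone, 1 value per experiment, and leaving out each replicate or cultivar. Array regions of 20 rows by 10 columns were scanned for dark patches, called where over 20% of bright spots lay more than 3 log2 units below the cultivar's other arrays. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for reading, permutation tests and plots. No 2 arrays of a group held the same values: correlations within groups ran from 0.917 to 0.979 over 31 pairs, and the smallest SD of a difference between arrays of a group was 0.605 log2 units. For 30 of the 33 arrays the closest array was of the same cultivar.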

Results

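Transcript levels were measured in leaves of 6 rice cultivars, of which CT9993, M202 and Nipponbare belong to the subspecies japonica and IR57311, IR62266 and IR72 to the subspecies indica. Control plants were labelled 28 °C by day and 21 °C by night, and plants at high night temperature (HNT) 30 °C by day and 28 °C by night. The chamber settings given beside these values were 26 and 22 °C for control and 28 and 28 °C for HNT, so that days were warmer too. The treatment began 25 days after sowing and lasted 23 days under 12 h of light, and leaves were taken at 48 days. Each array held a pool of 5 plants of 1 cultivar, and there were 3 arrays per cultivar and treatment from separate growth experiments, except 1 for IR62266 control and 2 for Nipponbare control. On the 33 arrays 57.1% to 74.7% of spots were well above background, and 20577 genes were tested, 12914 of them well above background on all arrays. Values are log2 differences with the standard error (SE), and adjusted p-values come from limma.

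Leaf transcript profiles differed first between the subspecies and next between 1 HNT experiment and all other experiments. On the first principal component, which held 35.4% of the variance, indica arrays scored 61.5 to 129.5 and japonica arrays -114.3 to -30.9. On the second component, with 13.7%, the arrays of HNT experiment 3 scored 92.9 to 117.8 and all other arrays -65.9 to 39.0. Ribosomal protein genes had a median difference from the controls of -0.16 and -0.27 in HNT experiments 1 and 2 and of -1.17 in experiment 3. Averaged over cultivars, 1390, 1700 and 5442 genes lay over 2-fold from the controls in HNT experiments 1, 2 and 3. In experiment 3, 5113 genes were higher and 5381 lower than in the other HNT experiments (limma), and 11795 genes differed among the HNT experiments against 2329 among the control experiments. HNT experiments 1 and 2 were not alike either. Set against the other 2 HNT experiments, experiment 3 included, 8930 genes stood apart in experiment 1 and 4319 in experiment 2. On deviations from the mean of all experiments, HNT experiment 1 correlated at -0.12 and -0.27 with HNT experiments 2 and 3. With control experiments 1, 2 and 3 it correlated at -0.05, -0.48 and 0.05. Of the arrays of HNT experiment 3, 5 were of series GE1_105 and 1 of series GE1_107, against 4 and 2 in experiment 1 and 1 and 5 in experiment 2.

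**Figure D1:**
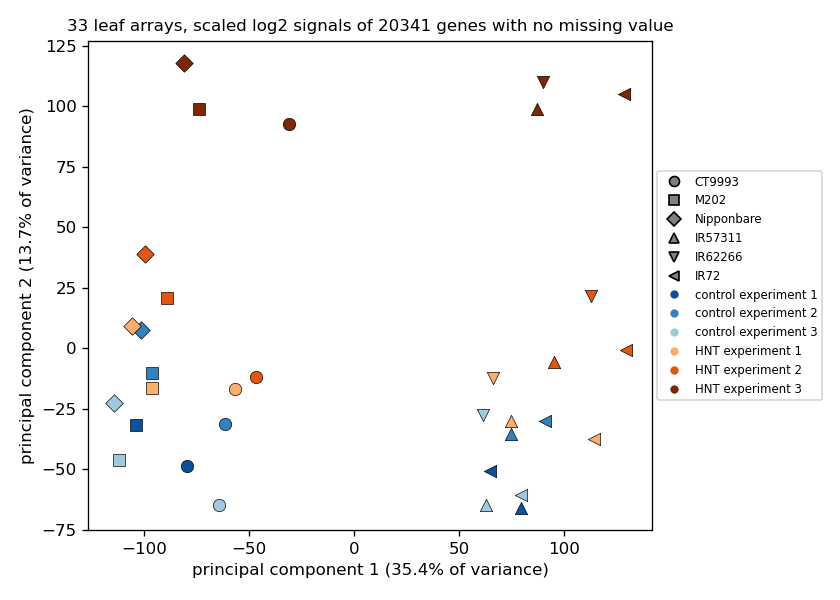
Scores of the 33 leaf arrays on the first (35.4% of variance) and second (13.7%) principal components of the scaled log2 signals, with 1 symbol per array, its shape giving the cultivar and its colour the growth experiment. Indica arrays sit at 61.5 or more on the horizontal axis and japonica arrays at -30.9 or less, and the arrays of HNT experiment 3 sit at 92.9 or more on the vertical axis.

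The first comparison asked how leaf transcripts of rice differ between high and control night temperature on average over the 6 cultivars. Its SEs and adjusted p-values rest on 1 correlation within experiments shared by all genes (0.421). They do not measure each gene's own spread between experiments. With 1 value per experiment limma called 0 genes (smallest adjusted p 0.126). Among the largest rises were 2 genes of the Tify family, which holds the JAZ repressors of jasmonate signalling. Os03g0181100 was 9.55-fold higher (3.26 ± 0.77, adjusted p = 0.0317) and Os10g0392400 9.29-fold higher (3.22 ± 0.68, adjusted p = 0.0210). Phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis, rose 6.66-fold at Os04g0518400 (2.74 ± 0.41, adjusted p = 0.00668). The largest rise was that of the amino acid carrier-like gene Os01g0882800 (12.1-fold, 3.60 ± 0.56, adjusted p = 0.00809), whose probe was well above background on 2 of 15 control and 17 of 18 HNT arrays. Os01g0705700, annotated as similar to the cold-response regulator ICE1, was 11.4-fold higher (3.51 ± 0.68, adjusted p = 0.0165). Gibberellin 2-oxidase 4 (Os05g0514600), which inactivates gibberellins, was 7.33-fold higher (2.87 ± 0.64, adjusted p = 0.0248). The WRKY factor Os02g0181300 rose 7.19-fold, the cytochrome P450 Os11g0483000 7.48-fold and the protein kinase Os01g0699500 10.0-fold. The kinases Os01g0699600 and Os10g0468500 rose by 2.83 and 2.75 on the log2 scale. These 5 genes had adjusted p from 0.0152 to 0.0317. Os07g0154100, similar to maize Viviparous-14, an enzyme of abscisic acid synthesis, rose 7.00-fold with the same sign in 5 cultivars (adjusted p = 0.0495), with signal well above background on 5 of 15 control and 15 of 18 HNT arrays. For Os05g0514600 and Os11g0483000 this held on 7 of 15 control arrays and for Os10g0468500 on 8. The folds of these genes, of Os07g0154100 and of Os01g0882800 thus rest in part on signal near background, and so does the rank of Os01g0882800. The mean differences from the controls in HNT experiments 1, 2 and 3 were 3.78, 1.17 and 5.15 for Os03g0181100 and 2.93, 1.78 and 5.90 for Os01g0705700, and without experiment 3 the averages were 2.42 (adjusted p = 0.0469) and 2.38 (adjusted p = 0.00955). On build IRGSP5 the probe of Os01g0882800 lies on chromosome 1 at 40040285 to 40040344. That of Os01g0705700 lies on chromosome 1 at 31002793 to 31002852 and that of Os03g0181100 on chromosome 3 at 4248755 to 4248814. The probe of Os10g0392400 lies on chromosome 10 at 13566939 to 13566998, that of Os05g0514600 on chromosome 5 at 25611491 to 25611550, and that of Os04g0518400 on chromosome 4 at 26426260 to 26426319. The files give no exon or UTR for them.

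An RNA polymerase sigma factor gene, the light-regulated gene Lir1 and the nicotianamine synthase gene NAS3 were among the genes that fell on average over the cultivars. The sigma factor gene Os05g0589200 (in plants such factors direct a plastid RNA polymerase to promoters) was 8.24-fold lower (-3.04 ± 0.46, adjusted p = 0.00668; chromosome 5, 29460598 to 29460657). Lir1 (Os01g0102900), which codes for a chloroplast protein, was 5.14-fold lower (-2.36 ± 0.56, adjusted p = 0.0317; chromosome 1, 168423 to 168482). NAS3 (Os07g0689600), whose product makes a chelator of iron, was 5.24-fold lower (-2.39 ± 0.45, adjusted p = 0.0152; chromosome 7, 29984648 to 29984707). The largest falls were those of the dimethylaniline monooxygenase gene Os09g0548400 (15.2-fold, adjusted p = 0.0256), the EF-hand gene Os03g0411300 (12.2-fold, adjusted p = 0.0330) and Os07g0529600, similar to a pathogen-induced defence protein (11.9-fold, adjusted p = 0.0241). The glutamate formiminotransferase-like gene Os03g0582000 (-3.10 ± 0.68), the phosphoglycerate mutase-like gene Os01g0660900 (-2.75 ± 0.72) and the rhodanese-like gene Os09g0530000 (-2.68 ± 0.69) fell. So did the cinnamyl-alcohol dehydrogenase-like gene Os09g0400300 (-2.62 ± 0.69), the bile acid:sodium symporter Os12g0170300 (-2.57 ± 0.51) and the phosphoglucomutase-like gene Os06g0476200 (-2.45 ± 0.62), and all 6 had adjusted p from 0.0182 to 0.0447. Os03g0582000 was well above background on 7 of 18 HNT arrays. Some of these differences were uneven among the experiments, a spread that their adjusted p-values do not measure gene by gene. The mean differences from the controls in HNT experiments 1, 2 and 3 were -0.86, -4.46 and -6.50 for Os09g0548400, -0.07, -4.45 and -6.39 for Os03g0411300, and -0.41, -2.91 and -3.84 for Os01g0102900. Without HNT experiment 3, 11 of the 12 named rises (1.97 to 2.98) and 5 of the 12 named falls (-3.23 to -1.38) passed the threshold, and the fold moved by over 1.5 times for 10 of the 12 rises and 9 of the 12 falls. Without HNT experiment 2, 10 and 3 passed, without HNT experiment 1 all did, without control experiment 2, 3 and 2 did, and without control experiment 1 or 3 none did (adjusted p from 0.0818 to 0.482). The fold moved that far for 7 rises and 1 fall without HNT experiment 2, for 4 and 11 without HNT experiment 1, for 1 and 1 without control experiment 2, for 0 and 2 without control experiment 3 and for 0 and 0 without control experiment 1. Leaving out control experiment 3 removed the only control array of IR62266. That average was thus over the other cultivars alone.

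In total 559 genes changed on average over the cultivars, 322 up and 237 down, 396 of them at least 2-fold (limma with the experiment as a random block, 15 control and 18 HNT arrays). Without control experiment 1, 2 or 3 the count was 0 (2474 genes at an unadjusted p under 0.05), 83 and 0 (2100). Without HNT experiment 1, 2 or 3 it was 3531, 348 and 672, of which 553, 225 and 357 were among the 559. The average without control experiment 3 also left out IR62266, which had no other control array. With 1 value per experiment limma called 0 genes (3314 at an unadjusted p under 0.05, smallest adjusted p 0.126). Within series GE1_105 and GE1_107 alone, each with 4 cultivars, it called 0 and 0 (2119 and 2168 unadjusted). Left out in turn, the cultivars CT9993, M202, Nipponbare, IR57311 and IR72 lowered the count to 186, 72, 246, 99 and 169. Without the arrays CT9993 control 1 and IR62266 HNT 2, which carried faint signal of genes of another cultivar, it was 161.

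**Figure D2:**
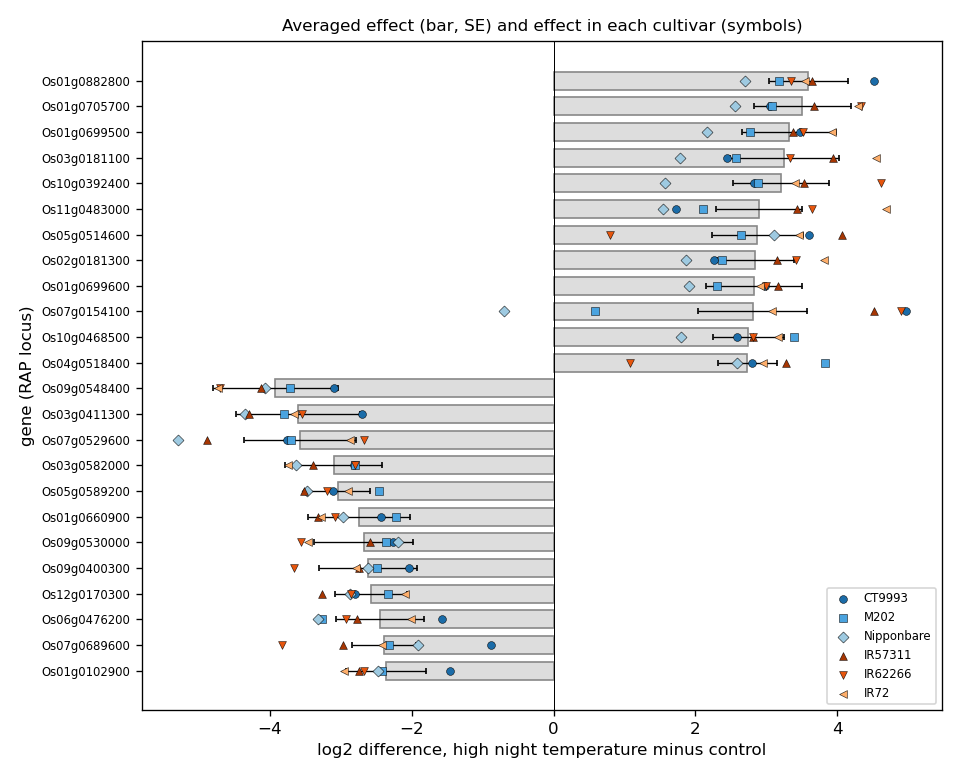
Log2 difference between HNT and control for the genes named in the averaged comparison, 1 row per gene, with the average over 6 cultivars as a bar with its SE and the effect in each cultivar as a symbol. The averages run from -3.92 for Os09g0548400 to 3.60 for Os01g0882800.

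Of 35 gene lists, those of jasmonate, phenylpropanoid and flavonoid, WRKY, NAC and cell wall genes were shifted up on average over the cultivars, and those of ribosomal proteins and of light harvesting were shifted down, by camera with a preset correlation. Only the phenylpropanoid and flavonoid list passed with an estimated correlation, and the other 6 had adjusted p = 0.0901 (jasmonate, WRKY and NAC), adjusted p = 0.323 (cell wall), adjusted p = 0.469 (ribosomal proteins) and adjusted p = 0.639 (light harvesting) with an estimated correlation. Of 34 measured jasmonate genes 9 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 1.05. The camera adjusted p was 1.29e-09, and adjusted p = 0.0901 with an estimated correlation. Among them were the synthesis genes lipoxygenase Os03g0700700 (1.54), allene oxide synthase Os03g0767000 and the 12-oxophytodienoate reductases Os06g0215900 (1.70) and Os06g0216300 (1.54), beside Tify genes. Of 55 phenylpropanoid and flavonoid genes 12 rose and 1 fell (24 and 3 adjusted over the list alone), with a median of 0.74. The camera adjusted p was 1.29e-09, and adjusted p = 0.00398 with an estimated correlation. Phenylalanine ammonia-lyase Os02g0627100 rose by 2.33 ± 0.47, cinnamoyl-CoA reductase Os08g0277200, an enzyme of lignin precursor synthesis, by 2.20 ± 0.47, and chalcone isomerase-like Os06g0203600, of flavonoid synthesis, by 1.92. Of 53 WRKY factors, regulators often linked to defence, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.41. The camera adjusted p was 3.60e-06, and adjusted p = 0.0901 with an estimated correlation. In HNT experiments 1, 2 and 3 the median difference from the controls was 0.77, 0.66 and 1.19 for jasmonate genes, 0.52, 0.74 and 0.59 for phenylpropanoid genes and 0.34, 0.13 and 0.69 for WRKY genes.

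The remaining shifted lists had few members past the threshold. Of 46 NAC factors 1 rose and 2 fell (2 and 2 adjusted over the list alone), among them Os08g0200600 (-1.77 ± 0.37). The NAC median was 0.49 and the camera adjusted p = 0.000317, and adjusted p = 0.0901 with an estimated correlation. After normexp background correction, which moved the median of all genes from -0.04 to -0.20, the NAC median was -0.03 while the test still pointed up. Of 58 cell wall genes 4 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.38 and a camera adjusted p = 0.00213, and adjusted p = 0.323 with an estimated correlation. The cell wall median was -0.21 after normexp. The expansins Os01g0823100 (2.17 ± 0.57) and Os10g0555600 (2.03 ± 0.51), which loosen cell walls, rose, and the cellulose synthase-like gene Os03g0377700 (-2.03 ± 0.52) fell. In HNT experiments 1, 2 and 3 the cell wall median was 0.55, 0.31 and 0.09. Without HNT experiment 1 the cell wall list had adjusted p = 0.167, and within series GE1_105 adjusted p = 0.260. Of 287 ribosomal protein genes 2 rose and 2 fell (0 and 0 adjusted over the list alone by limma, 131 at an unadjusted p under 0.05), with a median of -0.51 and a camera adjusted p = 9.96e-12, and adjusted p = 0.469 with an estimated correlation, and the median was lowest in HNT experiment 3 (-1.17). Of 39 light harvesting and photosystem genes 0 rose and 0 fell, with 0 and 0 adjusted over the list alone (limma, 1 unadjusted), and with a median of -0.50 and a camera adjusted p = 0.0137, and adjusted p = 0.639 with an estimated correlation. The light harvesting call was lost without control experiment 3 (adjusted p = 0.370), HNT experiment 1 (adjusted p = 0.0556) or HNT experiment 2 (adjusted p = 0.0948), and with quantile normalization (adjusted p = 0.246).

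Heat shock, clock and flowering genes as lists were not shifted on average. Of 59 heat shock protein genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.341). The chaperone gene HSP70 Os03g0277300 rose by 2.42 ± 0.56 (adjusted p = 0.0294). Of 16 listed heat shock factors, Os09g0456800 rose by 1.89 ± 0.33 (adjusted p = 0.0152, list adjusted p = 0.0587). Of 10 clock genes 0 changed in the averaged test by limma (5 at an unadjusted p under 0.05, 0 up and 3 down adjusted over the list alone, camera adjusted p = 0.480). GIGANTEA (Os01g0182600), a clock and flowering regulator, differed by -2.62 ± 0.73 (adjusted p = 0.0525), with -0.13, -2.26 and -5.50 in HNT experiments 1, 2 and 3. The pseudo-response regulators PRR37 and PRR73 differed by -1.90 ± 0.66 (adjusted p = 0.111) and -1.43 ± 0.49 (adjusted p = 0.103). In experiment 3 they stood at -4.65 and -3.64, LHY, a morning clock factor, at 1.00 and PRR1 at 1.46. Of 9 flowering genes 0 changed by limma (2 unadjusted, 0 up and 1 down adjusted over the list alone, camera adjusted p = 0.613). The photoperiod regulator Hd1 differed by 1.35 ± 0.54 (adjusted p = 0.152) and Ehd1 by 1.18 ± 0.63 (adjusted p = 0.281). Hd1 was well above background on 6 of 15 control and 14 of 18 HNT arrays. The florigen gene Hd3a, well above background on 6 and 11 of them, did not pass (adjusted p = 0.591), and DTH8 had adjusted p = 0.0744. Of the 8 measured members of the CBF/DREB1 list 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.0587). It was the ICE1-like gene Os01g0705700, of a class of regulators upstream of the cold-response CBF/DREB1 genes and not a CBF/DREB1 gene itself. Another ICE1-like gene (Os01g0928000, 0.01) and a CCAAT-binding factor gene (Os07g0608200, -0.10) were in the list by name. DREB1B differed by 1.58 ± 0.91 (adjusted p = 0.321), DREB1C, well above background on 6 of 15 control arrays, by 1.80 ± 1.21 (not past the threshold) and DREB1A by 0.06 ± 0.88 (adjusted p = 0.975).

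**Figure D3:**
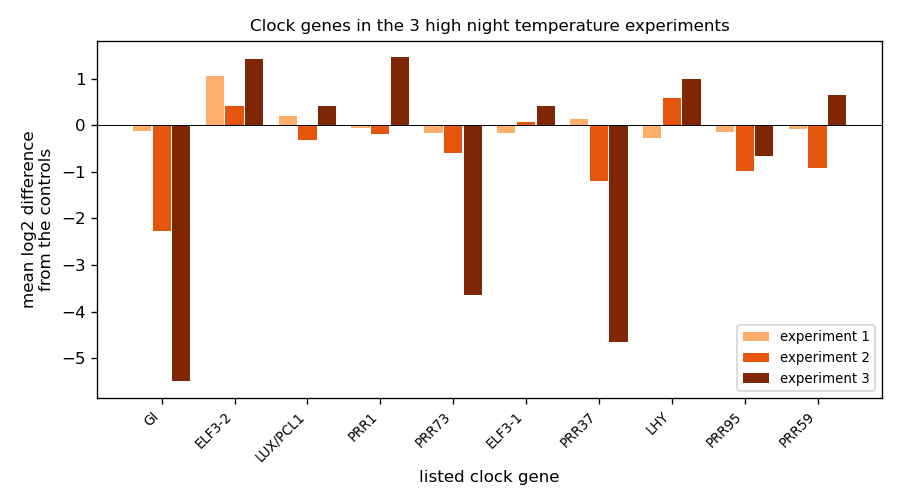
Mean log2 difference from the controls, over cultivars, of the listed clock genes in the 3 HNT experiments, 1 bar per gene and experiment, without error bars. Bars for GIGANTEA reach -0.13, -2.26 and -5.50 in experiments 1, 2 and 3, and those for LHY -0.27, 0.59 and 1.00.

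In CT9993 a lipid transfer protein gene rose and 2 cinnamyl-alcohol dehydrogenase genes fell at HNT. The lipid transfer protein gene Os05g0550300 rose by 4.72 ± 0.95 (adjusted p = 0.0329), chalcone isomerase-like Os12g0115700 by 3.63 ± 0.64 (adjusted p = 0.0198) and the cysteine and methionine metabolism gene Os10g0517500 by 3.51 ± 0.73 (adjusted p = 0.0356). All 3 CT9993 controls and 1 of 3 HNT arrays were of series GE1_107, and the fitted differences include the array series term. Without it the differences of these genes were 4.14 (adjusted p = 0.0549), 2.62 (adjusted p = 0.194) and 2.87 (adjusted p = 0.104), and of the other genes named for CT9993 Os05g0572700 (adjusted p = 0.178) and Os07g0410300 (adjusted p = 0.0860) did not pass either. The protein phosphatase 2C gene Os05g0572700 was at least 2.10-fold higher (adjusted p = 0.0454), with a reversed sign after normexp (-0.23). The cinnamyl-alcohol dehydrogenase genes Os09g0399800, of an enzyme family of lignin synthesis, and Os09g0400400 were at least 29.1-fold (adjusted p = 9.20e-05) and at least 9.04-fold lower (adjusted p = 0.000443). The ethylene response factor gene Os07g0410300 was at least 17.5-fold lower (adjusted p = 0.0329), and the glutathione transferase GSTF1 (Os01g0370900) fell by 3.77 ± 0.77 (adjusted p = 0.0329). Os05g0550300 was well above background on 1 of 3 controls and Os01g0370900 on 1 of 3 HNT arrays, so that their differences rest mostly on signal near background in that group. In total 65 genes changed (37 up and 28 down, 3 against 3 arrays). The count was 10 without control 1 (the array with faint signal of Nipponbare genes), 17 without control 2, 35 without HNT 1 and 2 without HNT 3, and limma on series GE1_107 alone called 0 (924 unadjusted).

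In M202 a flavonoid synthesis gene and WRKY factor genes rose at HNT. The flavanone 3-hydroxylase-like gene Os04g0581000, of flavonoid synthesis, rose by 4.88 ± 0.86 (adjusted p = 0.00622), WRKY62 (Os09g0417800) by 4.28 ± 0.94 (adjusted p = 0.0309) and phenylalanine ammonia-lyase Os04g0518400 by 3.83 ± 0.56 (adjusted p = 0.00128). The WRKY factor gene Os11g0117500 was at least 5.54-fold higher (adjusted p = 0.00106). The EIL3-like gene Os08g0508700, of the ethylene-insensitive family of transcription factors, was at least 6.63-fold lower (adjusted p = 6.89e-05), and the RING/FYVE/PHD zinc finger gene Os07g0631200 fell by 2.33 ± 0.52 (adjusted p = 0.0346). The gene similar to pyrophosphate-dependent phosphofructokinase Os02g0714200, of glycolysis, was 4.61-fold lower (adjusted p = 0.0297), and the nodulin-like gene Os05g0475700 fell by 2.09 ± 0.49 (adjusted p = 0.0450). Os04g0581000 and Os09g0417800 were well above background on 1 of 3 controls and Os07g0631200 on 1 of 3 HNT arrays, so that the size of these differences is uncertain. Without the array series term Os07g0631200 (adjusted p = 0.0516) and Os02g0714200 (adjusted p = 0.100) did not pass. In total 127 genes changed (100 up and 27 down, 3 against 3 arrays). The count was 47 without control 1, 80 without control 3, 78 without HNT 1, 46 without HNT 2 and 74 without HNT 3, and within series GE1_105 and GE1_107 it was 1 and 2.

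In Nipponbare 1 gene changed, Os04g0652600, a conserved hypothetical gene on chromosome 4 (33750375 to 33750434) outside the naming rule and chosen after its value was seen, with a difference of -2.14 (adjusted p = 0.00862, 3 against 2 arrays). At an unadjusted p under 0.05 there were 1357 genes. After quantile normalization 33 genes passed, 60.6% of them higher against 0% of the main call. The count was 221 without control 2, 4 without control 3, 3 without HNT 1 and 3 without HNT 2, and within series GE1_105 it was 85. Control 3 had 3 regions with dark patches.

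In IR57311 4 genes changed, 2 up and 2 down. Phenylalanine ammonia-lyase Os04g0518400 rose by 3.28 ± 0.57 (adjusted p = 0.0426), and the B-box zinc finger gene Os06g0713000, of a family of light-signalling regulators, was 4.36-fold higher (adjusted p = 0.00540). The ankyrin repeat gene Os07g0532500 fell by 2.19 ± 0.37 (adjusted p = 0.0338) and Os02g0597800, annotated with a nuclear hormone receptor ligand-binding domain, by 1.49 ± 0.24 (adjusted p = 0.0206). Os06g0713000 was well above background on 2 of 3 controls and Os07g0532500 on 2 of 3 HNT arrays. The count was 0 without control 1, control 3 or HNT 3 (limma, 1554, 1179 and 1140 genes unadjusted), 9 without control 2, 16 without HNT 1 and 2 without HNT 2, over 3 against 3 arrays. Within series GE1_105 and GE1_107 it was 0 (969 unadjusted) and 1.

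In IR62266 28 genes passed the test, 15 higher and 13 lower at HNT, but against a single control array, so that the treatment and any peculiarity of that array cannot be told apart. Of 69 genes on in some and off in other arrays of this cultivar, 27 (39.1%) split exactly by treatment, against 0% to 3.85% in the other cultivars. Here such a split needs only the single control array to differ, and elsewhere 2 or 3 controls must. The shares therefore cannot be compared as a measure of the treatment. Of the 28 genes 6 were among those 69, Os03g0277300, Os06g0244000, Os09g0544000 and Os11g0562100 among them. The chaperone gene HSP70 Os03g0277300 was at least 43.9-fold higher (adjusted p = 0.0157), the transferase gene Os09g0544000 at least 16.3-fold (adjusted p = 0.0127), the methyltransferase gene Os06g0244000 at least 9.56-fold (adjusted p = 0.00969) and the SEB-4-like gene Os02g0755400 at least 5.81-fold higher (adjusted p = 0.00969). The gene similar to cycloartenol synthase, an enzyme of sterol synthesis, Os11g0562100 was at least 10.5-fold lower (adjusted p = 0.0157), and the leucine-rich repeat gene Os06g0140200 at least 6.13-fold lower (adjusted p = 0.00709). The cytochrome P450 Os01g0803800 was at least 3.00-fold lower (adjusted p = 0.0157), and the kinase Os02g0215700 stood at -3.38 ± 0.63 (adjusted p = 0.0200), with 1 of 3 HNT arrays well above background. Within series GE1_105 the count was 5. HNT 2 carried faint signal of genes of IR72, and without that array the count was 21.

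In IR72 73 genes changed, 39 up and 34 down. The nicotianamine synthase NAS1 (Os03g0307300), of iron chelator synthesis, rose by 5.56 ± 1.10 (adjusted p = 0.0317), and the jasmonate-induced protein-like gene Os12g0247700 by 7.92 ± 1.65 (adjusted p = 0.0384). Both probes were well above background on 1 of 3 controls and 3 of 3 HNT arrays. All IR72 HNT arrays and 1 of 3 controls were of series GE1_107, and the fitted differences include the array series term. The measured means were -5.68 in control and -1.85 at HNT for Os03g0307300 and -5.72 and 1.00 for Os12g0247700, and without that term the differences were 3.83 (adjusted p = 0.193) and 6.72 (adjusted p = 0.0694). The resistance gene-like Os07g0521600 and the cytochrome P450 Os07g0520300 were at least 6.82-fold (adjusted p = 0.00251) and at least 4.07-fold higher (adjusted p = 0.000794). These were the 2 genes among the 84 on in some and off in other arrays of this cultivar that split exactly by treatment, and their probes lie near each other on chromosome 7, from 20824415 and from 20746709. The jasmonate-induced protein-like gene Os10g0132300 and the MIZ zinc finger gene Os06g0164000 were at least 8.92-fold and 9.05-fold lower (adjusted p = 0.0317 for both). The NB-ARC resistance gene-like Os09g0365300 stood at -4.37 ± 0.65 (adjusted p = 0.00251), and the Remorin gene Os02g0642200 was at least 2.83-fold lower (adjusted p = 0.0245). The probes of these 4 lower genes were well above background on 2 of 3 controls. Os10g0132300, Os06g0164000 and Os09g0365300 were among 15 genes on in controls 1 and 3 alone, so that they were off in control 2 as well and did not split by treatment. In all, 9 of the 73 genes were among the 84. The count was 15 without control 1, 10 without HNT 1, 288 without HNT 2, 20 without HNT 3, and 10 without controls 1 and 3, which shared signal of genes off in control 2. Within series GE1_107 it was 9.

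Phenylpropanoid and flavonoid, jasmonate and WRKY genes were shifted up in each of the 6 cultivars by camera, and ribosomal protein genes were shifted down in all but IR57311 (adjusted p = 0.645). For phenylpropanoid genes the adjusted p was 0.0245 in CT9993, 0.00519 in M202, 0.00369 in Nipponbare, 0.0142 in IR57311, 0.0887 in IR62266 and 0.565 in IR72 with an estimated correlation. The lowest adjusted p over cultivars was 0.111 for jasmonate genes, 0.120 for WRKY genes and 0.589 for ribosomal protein genes with an estimated correlation. Across genes, which are not independent replicates, the effect in a cultivar correlated with the average over the other cultivars with r from 0.575 (Nipponbare) to 0.761 (IR57311), where cultivars shared growth experiments. After normexp background correction limma called 0 genes in CT9993, M202, Nipponbare, IR57311 and IR62266 (783, 288, 690, 414 and 397 at an unadjusted p under 0.05) and 1 in IR72. Fitted on the arrays of 1 cultivar alone, limma called 0 genes in CT9993, Nipponbare and IR57311 (2336, 832 and 1592 unadjusted), 15 in M202 and 2 in IR72.

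The next comparison asked whether the HNT effect differed among the cultivars. The cinnamyl-alcohol dehydrogenase gene Os09g0399800, of a family of lignin synthesis enzymes, had the lowest p (F = 18.1, adjusted p = 0.00148), with signal well above background on all 3 CT9993 controls, on no CT9993 HNT array and elsewhere only on 1 of 3 arrays in each IR57311 group. The transporter gene Os09g0371200, of the major facilitator family (F = 16.5, adjusted p = 0.00268), differed by -1.76 in CT9993 and by 1.60 in M202. The gene Os11g0669100, similar to a calmodulin-binding protein (F = 15.2, adjusted p = 0.00410), differed by 1.76 in M202 and -1.04 in CT9993 (these genes were well above background on 4 of 15 control and 11 and 7 of 18 HNT arrays), and the eggshell protein-like gene Os02g0303500 (F = 13.8, adjusted p = 0.00747) by 3.28 in M202 and 0.03 in IR72. The auxin response gene Os02g0228900, similar to IAA18, a repressor of auxin signalling (F = 12.5, adjusted p = 0.0116), differed by 0.71 in CT9993 and by -2.12 in IR62266. The FYVE/PHD zinc finger gene Os04g0450000 (F = 12.3, adjusted p = 0.0116) and the gene similar to aldehyde oxidase-2, Os07g0281800 (F = 11.8, adjusted p = 0.0127), differed most in IR62266, the cultivar with 1 control array, by 2.87 and 3.15. The cytochrome P450 Os07g0520300 (F = 15.1), the methyltransferase Os06g0244000 (F = 12.5) and the kinase Os02g0215700 (F = 12.1) complete the 10 genes with the lowest p, of which Os07g0520300 did not pass without the array series term (adjusted p = 0.0521). In total 75 genes differed in their HNT effect (limma moderated F-test). The cultivar farthest from the others was IR62266 (1 control array) for 27, M202 for 18, IR72 for 12, CT9993 for 11, Nipponbare for 7 and IR57311 for 0. The count was 13 without HNT experiment 3, 22 without IR72, 46 without IR72 controls 1 and 3 and 24 without CT9993 control 1 and IR62266 HNT 2, and after normexp limma called 0 (73 unadjusted).

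Between the subspecies the HNT effect differed for 0 genes (limma, 1 value per cultivar, 3 indica against 3 japonica; 1920 genes at an unadjusted p under 0.05). The simulation recovered 45% of 4-fold and 0% of 2-fold differences in this comparison. A contrast over arrays, which takes arrays and not cultivars as replicates, called 2 genes (921 unadjusted).

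Over both treatments the wall-associated kinase-like gene Os06g0142500 was higher in indica than in japonica by 7.80 ± 0.63 (adjusted p = 0.00183), and the leucine-rich repeat gene Os11g0597400 by 7.06 ± 1.19 (adjusted p = 0.0195). The beta-amyrin synthase-like gene Os02g0140400, of triterpene synthesis, was higher by 6.62 ± 0.81 (adjusted p = 0.00720), the integrase domain gene Os11g0224300 by 6.56 ± 0.87 (adjusted p = 0.00961) and the transferase gene Os08g0111800 by 5.32 ± 0.25 (adjusted p = 0.000283). These 5 genes were well above background on all 16 indica arrays, and on 6, 13, 4, 5 and 4 of 17 japonica arrays. The prenyltransferase gene Os01g0684800, well above background on 16 of 16 indica and 0 of 17 japonica arrays, was at least 14.0-fold higher (adjusted p = 0.000188). The gene similar to HC toxin reductase Os07g0601000 was lower in indica (-9.99 ± 0.16, adjusted p = 4.61e-05), as were the CBS domain gene Os04g0136700 (-9.51 ± 0.76), the ankyrin gene Os11g0251400 (-8.25 ± 0.49) and the NB-ARC resistance gene-like Os11g0606400 (-8.22 ± 0.40), with adjusted p from 0.000314 to 0.00179. These were well above background on all 17 japonica arrays and on 4, 1, 2 and 1 of 16 indica arrays. Where most arrays of a subspecies were near background, the size of a difference and its rank are uncertain. The methionine aminopeptidase-like gene Os12g0628500 and the PDZ domain gene Os09g0436700, both on 0 of 16 indica arrays, were at least 102-fold (adjusted p = 0.000141) and at least 77.8-fold lower (adjusted p = 0.000181).

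In total 2823 genes differed in level between the subspecies, 1147 higher and 1676 lower in indica, 1664 of them at least 2-fold (limma, 3 cultivars against 3). The share higher in indica was 40.6%, and 53.4% after quantile normalization, so the balance between directions depends on the scaling. Left out in turn, M202, Nipponbare, IR57311, IR62266 and IR72 lowered the count to 1534, 1799, 1487, 1803 and 1348, and after normexp it was 182. A lower signal can also come from sequence differences under a probe.

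Under control conditions genes with signal in some cultivars and none above background in others led the differences among the 6 cultivars. Os12g0628500 (F = 303, adjusted p = 5.54e-16) stood at 1.25 ± 0.18 in CT9993, 1.20 ± 0.06 in M202 (SD, n = 3) and 0.98 in Nipponbare on the scaled log2 axis, and was not well above background in indica. Os11g0597400 (F = 277, adjusted p = 9.42e-16) stood at 5.25 ± 0.11 in IR57311, 4.58 ± 0.16 in IR72 (SD, n = 3) and 1.61 in IR62266, against -4.76 in CT9993 and -2.24 in Nipponbare, and was not well above background in M202. The thioredoxin fold gene Os01g0184800 (F = 266), the gene similar to phosphoenolpyruvate carboxykinase Os10g0204300, an enzyme of gluconeogenesis (F = 221), and the PDZ domain gene Os09g0436700 (F = 211) were well above background in japonica alone among the control groups. The ribonuclease H fold gene Os01g0944200 (F = 264) stood at 2.99 in CT9993, 2.88 in M202, 3.21 in Nipponbare and 3.08 in IR57311, and was not well above background in IR62266 and IR72 controls. In total 5795 of 20577 genes differed among the control groups (limma moderated F-test, 15 arrays, with IR62266 at 1 and Nipponbare at 2 arrays). The count was 848 after normexp and 2246 over the genes well above background on all arrays.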

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

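All tests of explanations below were chosen after the result was seen, except those of neighbouring genes in IR57311 and of other splits of the samples. HNT experiment 3 stood apart from the other experiments in the number of genes over 2-fold from the controls (5442, next 1700). The HNT 3 arrays of CT9993, M202, IR57311 and IR72 had more spots far below the other arrays of their cultivar (284, 289, 413 and 367) than the remaining arrays of that cultivar. Of 13 sets tested, 5 had such an outlier. All 5 were HNT experiment 3 or its arrays, so they are not independent of each other and cannot be set against a chance rate. The HNT effect differed among cultivars for 75 genes by the interaction test. Of the 33 columns of the authors' value table, 8 did not hold the values of their own array.

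Each HNT experiment was set against the other 2, and 8930 genes stood apart in experiment 1 and 4319 in experiment 2. In HNT experiment 3, 10494 genes stood apart from the other HNT experiments, clock genes among them. Dimmer arrays are argued against, because 10101 genes (96.3%) still stood apart with the percent of spots well above background in the model. Within array series GE1_105, with 4, 1 and 5 arrays of experiments 1, 2 and 3, 4543 genes (43.3%) did so. Of these, 3068 were over 2-fold apart, against 3923 over all arrays. Standing apart within 1 series argues against the array series for these genes. Over fewer arrays, the lower count cannot tell whether the series added to the rest. For the clock genes the temperature itself, acting alike in each experiment, is argued against by a median absolute shift of 0.151 in experiment 1 against 0.594 and 1.21 in experiments 2 and 3. Another time of day or clock phase at sampling may contribute, as a hypothesis, but the hour of harvest is not given. In experiment 3, 5 of 10 clock genes, 2 higher and 3 lower, were over 2-fold apart against 3918 of 20567 other genes (two-sided Fisher's exact p = 0.0270). That test counts the same genes and experiment that raised the question and takes genes as independent, so it cannot decide it.

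In IR72, 84 genes were on in some arrays and off in others by at least 3 log2 units. The temperature itself is argued against, since 2.38% of them split exactly by treatment. The 15 genes on in controls 1 and 3 alone, the 2 IR72 arrays of series GE1_105, differed between the series by a median of 6.56 in IR72, which follows from their choice. In the other cultivars the median was -0.079 (SD 0.698, 56 values). Only cultivars with the gene well above background on all arrays counted there, so a gene off in 1 series was left out beforehand. Where these genes were on throughout, the series differed little, but the array series as a cause in IR72 was not settled. Plants of different genotype in the pools are a candidate explanation: 35 of 67 pairs of such genes within 1 Mb shared their pattern, against 12.6 when patterns were shuffled (one-sided permutation p = 0.00014, adjusted 0.00084 over 6 cultivars). The same test gave an adjusted p of 0.00804 in CT9993, where 42 of 61 such genes were on in control 1 alone, the array with faint signal of Nipponbare genes, and was not passed in IR62266 (adjusted p = 0.0637), IR57311 (83 genes, permutation p = 0.0501, adjusted 0.0751), Nipponbare (adjusted p = 0.613) or M202 (adjusted p = 1).

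On CT9993 control 1, 124 of 152 genes (81.6%, exact 95% interval 74.5% to 87.4%) that were on in Nipponbare and off in the other CT9993 arrays were well above background, against 1 of 22 genes (4.55%) off in Nipponbare, at a median of 6.01% of the Nipponbare level. On IR62266 HNT 2 the shares were 51 of 56 genes (91.1%, 80.4% to 97.0%) on in IR72 and 10 of 222 (4.50%) off in it, at 5.02% of the IR72 level. Both are consistent with RNA or plants of another cultivar in the sample, and no biological explanation was tested for these arrays. A leak from another array of the slide is argued against for CT9993 control 1, where 5% (1 of 20) of genes on in a cultivar of the slide and off in Nipponbare were well above background. For IR62266 HNT 2 a leak cannot be told apart from RNA of IR72 in the sample, because 1 array of IR72 lay on the same slide, and since CT9993 control 1 lay on that slide too, a handling step shared by the slide stays open, untested, for both.

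Other splits of the same 6 experiments, arrays or cultivars into 3 and 3 number 10, too few for a share under 0.05. For the averaged effect 2 of 10 splits gave as many genes, the real one (559) and 1 that set control experiments 1 and 3 and HNT experiment 1 against the rest (2204), which points to a structure of the experiments. For CT9993, M202 and IR72 1 of 10 splits, the real one, gave as many (65, 127 and 73, highest other 0, 0 and 6), and for IR57311 3 splits did (4, highest other 21). For the subspecies difference in the HNT effect all 10 splits gave 0, and for that in level 1 split did, the real one (2823, highest other 11).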

How the results depend on the processing

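The averaged effect, the effects in single cultivars and the interaction moved with most choices. Alternatives without array patches, without HNT experiment 3 or IR72 controls, and without CT9993 control 1 and IR62266 HNT 2 were chosen after seeing the data. Of the counts under an alternative 102 stayed within 1.5 times of the main count, 32 were higher and 95 lower. The 102 include counts of 0 against a main count of 0, as for the subspecies difference in the HNT effect, and the counts of shifted lists. They thus overstate how stable the calls of genes were. The 88 named results, each a gene in 1 comparison so that some genes count more than once, gave 665 values under alternatives. Of these values 428 kept direction and side of the threshold, 236 lost the call and 1 reversed (Os05g0572700 in CT9993 after normexp, -0.23, adjusted p = 0.939). Of the 88 results 73 lost the call at least once. Across settings 7 to 10 lists were shifted by camera with a preset correlation, against 7. Camera with an estimated correlation was run in the main setting alone, where 1 list passed, so its dependence on the processing was not tested. Unless stated, the cause was not tested. After normexp, which models signal over background, the SD of the log2 values of an array was 0.807 to 2.86 log2 units against 3.20 to 4.18.

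With quantile normalization counts were 33 in Nipponbare (60.6% higher against 0%), 7 in IR57311, 46 in IR62266, 24 in IR72 and 123 for the interaction. With normexp limma called 0 genes in CT9993, M202, Nipponbare, IR57311, IR62266 and for the interaction (783, 288, 690, 414, 397 and 73 unadjusted), 1 in IR72 (0% higher against 53.4%), 182 for the subspecies level and 848 for control groups. With the authors' value table, which gave no value for IR57311, counts were 49 averaged, 3 in CT9993 (33.3% higher against 56.9%), 27 in M202, 0 in Nipponbare and IR62266 (679 and 937 unadjusted), 7 in IR72 (71.4% higher against 53.4%). It gave 8 for the interaction, 721 for level and 2322 for control groups, over fewer arrays. Without a filter on dim probes counts were 1132 averaged, 43 in CT9993, 1 in IR57311, 56 in IR62266, 34 in IR72 and 19 for the interaction. Over genes well above background on all arrays, which are fewer, they were 194 averaged, 0 in CT9993, Nipponbare and IR62266 (1089, 752 and 922 unadjusted), 48 in M202, 7 in IR57311, 5 in IR72, 10 for the interaction and 2246 for control groups. With a difference of at least 1 log2 unit required, 1664 genes differed in level between subspecies.

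Without the array series term counts were 8 in IR57311 and 129 for the interaction. With the slide as a random block they were 135 in CT9993, 10 in IR57311 and 378 in IR72. In the averaged effect and the interaction that block (estimated correlation -0.164) takes the place of the experiment block, and counts were 6085 and 20, against 6756 and 5 with no block. With the slide as a fixed block they were 2 averaged, 2 in CT9993, 6 in M202, 0 in Nipponbare and IR57311 (1217 and 874 unadjusted), 1 in IR62266 and IR72, 6 for the interaction and 2715 for control groups. Within series GE1_105 limma called 0 averaged, 1 in M202, 85 in Nipponbare, 0 in IR57311 and 5 in IR62266 (2119 and 969 unadjusted beside the zeros). Within GE1_107 it called 0 averaged, 0 in CT9993, 2 in M202, 1 in IR57311 and 9 in IR72 (2168 and 924 unadjusted). With 1 value per experiment 0 genes passed in the averaged effect (limma, 3314 unadjusted). On the arrays of 1 cultivar alone limma called 0 in CT9993, Nipponbare and IR57311 (2336, 832 and 1592 unadjusted), 15 in M202 and 2 in IR72. With arrays in place of cultivars as replicates, 2 genes differed between subspecies in the HNT effect and 9451 in level.

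With the replicate number as a block counts were 2286 averaged, 188 in CT9993, 364 in M202, 16 in Nipponbare, 113 in IR57311, 88 in IR62266, 184 in IR72 and 25 for the interaction. Same-numbered control and HNT arrays correlated at -0.22 to 0.27 over 14 pairs, over 0.1 in 7, and 5 of 15 HNT arrays correlated best with their own number. The correlations were positive for numbers 1 and 2 and negative for number 3 in every cultivar with such a pair. They were taken on deviations from the group mean, which the large shift of HNT experiment 3 moves for the other HNT arrays as well. Pairing by number was thus neither shown nor excluded.

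Leaving out 1 experiment, array or cultivar gave 0 to 3531 genes averaged, 2 to 77 in CT9993, 46 to 111 in M202, 1 to 221 in Nipponbare, 0 to 16 in IR57311, 19 to 33 in IR62266, 10 to 288 in IR72, 1348 to 3869 for the subspecies level, 0 for the subspecies difference in effect (limma, 1208 to 2329 unadjusted) and 5237 to 6098 for control groups. For the lowest, without control experiment 1 or 3 the averaged count was 0 (2474 and 2100 unadjusted), and without IR57311 control 1, control 3 or HNT 3 it was 0 in IR57311 (1554, 1179 and 1140). Where an arm was left with 1 array, that array was assumed to vary like the other groups. Without control experiment 3 IR62266 had no control array, so it was left out of that average. Without CT9993 control 1 and IR62266 HNT 2 counts were 161 averaged and 24 for the interaction, and without HNT experiment 3, IR72, or IR72 controls 1 and 3 the interaction count was 13, 22 and 46, and without these controls that of IR72 was 10. Without spots in dark patches counts moved by less than 1.5 times.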

Other observations

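Single genes of nitrogen assimilation, chlorophyll breakdown and respiration were among further changes in the averaged HNT effect, although their lists were not shifted as a whole. Over all genes 559 of 20577 were called. A single call in a list of 33 or more genes lies near or below that share and shows no change of the pathway. Of 18 amino acid and GABA genes 0 rose and 2 fell (1 and 2 adjusted over the list alone): NADH-dependent glutamate synthase 2 (Os05g0555600), of ammonium assimilation, fell by 2.29 ± 0.55 (adjusted p = 0.0317), and pyrroline-5-carboxylate reductase (Os01g0948400), of proline synthesis, by 0.93 ± 0.20 (adjusted p = 0.0232). Of 5 chlorophyll breakdown genes SGR (Os09g0532000), the stay-green gene needed to degrade chlorophyll, rose by 1.56 ± 0.38 (adjusted p = 0.0339). The alternative oxidase gene AOX1a (Os04g0600200), of a respiratory bypass, rose by 0.84 ± 0.22 (adjusted p = 0.0462), 1 of 33 mitochondrial electron transport genes, and malate dehydrogenase Os08g0434300 by 1.25 (adjusted p = 0.0368), 1 of 36 tricarboxylic acid cycle genes. Of 49 starch and sucrose genes the beta-fructofuranosidase (invertase) Os04g0535600 rose by 1.10, and of 13 inositol, raffinose and trehalose genes Os01g0170000 rose by 1.11 (adjusted p = 0.0457). Of 30 carbon fixation genes 0 changed, and 0 adjusted over the list alone (limma, 3 unadjusted, camera adjusted p = 0.228).

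Hormone and stress lists also held single changes. Set against 559 called of 20577 genes, a single call in a list of 43 or more genes is below the share over all genes. Such calls are not read as a change of the list. Of 8 cytokinin genes the cytokinin oxidase 2-like gene Os05g0374200, of cytokinin breakdown, fell by 1.51 (adjusted p = 0.0359) and Os05g0127300 rose by 1.48 (adjusted p = 0.0439). The ethylene synthesis gene ACC oxidase Os05g0149400 rose by 1.12 ± 0.27 (adjusted p = 0.0317), 1 of 7, and of 44 auxin response genes 2 fell and 0 rose. Of 43 glutathione transferases Os01g0950300 rose by 1.16, of 38 phosphate homeostasis genes 2 rose (5 adjusted over the list alone), of 14 iron homeostasis genes NAS3 fell, of 15 terpenoid genes Os08g0139700 rose by 1.01 and of 114 resistance genes Os02g0612200 by 1.10. Among abscisic acid (15 genes), gibberellin (12), late embryogenesis abundant (19), antioxidant (35) and pathogenesis-related genes (80) limma called 0 in the averaged effect (5, 5, 3, 5 and 15 at an unadjusted p under 0.05). The lists take members by the words of the annotation and do not hold gibberellin 2-oxidase 4 (Os05g0514600) or the Viviparous-14-like gene Os07g0154100, which rose in this effect. Adjusted over the list alone, 1 gibberellin gene was higher and 2 were lower, and the other 4 lists had 0. The lists of other tissue were not shifted: 0 of 6 seed storage genes (2 unadjusted, 0 adjusted over the list alone, adjusted p = 0.525), 0 of 4 floral organ genes by limma (1 unadjusted, 1 up adjusted over the list alone, adjusted p = 0.480) and 1 of 95 cell division genes, Os05g0325200 (-1.10, list adjusted p = 0.477). The median, mean and test of the tricarboxylic acid, mitochondrial, gibberellin, resistance, antioxidant, glutathione transferase and seed storage lists differed in sign. By fry, which tests whether a list's genes moved together, 8 of the 35 lists passed in the averaged effect, and 19 did for changes in either direction.

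Other values stood outside the comparisons. On Nipponbare control 3, 3 regions had 24.3% to 38.5% of bright spots far below the other arrays, and on IR57311 control 1, 1 region had 26.3%. The share of genes of another cultivar well above background reached at most 40% on the arrays other than CT9993 control 1 and IR62266 HNT 2. On IR72 control 3 it was 10 of 25 genes on in IR57311, against 10 of 232 (4.31%) off in it. On Nipponbare control 2 it was 12 of 30 genes on in IR57311, against 4 of 21 (19.0%) off in it. The source of this signal was not tested, and these arrays cannot be called free of it. The array series differed at 250 genes (limma).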
